A study of Homo sapiens with 3 samples.

How the data were processed

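ATAC-seq libraries were made from 100000 macrophages each and sequenced with 100-bp paired reads, per the labels' protocols. The labels' protocols state 2 biological replicates per condition, merged for footprint analyses; whether the peaks were called on merged reads is not given in the sources used here. Samples were grouped by the infection named in their characteristics. Each infection entered with 1 peak list, and the non-infected sample was not used here.

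Trimmomatic 0.36, BWA 0.7.12, SAMtools 1.3.1, Picard 2.0.1 and MACS2 2.1.0 are named with build hg19 in the submitters' processing notes. Their roles, order and settings are not given in the sources used here, including whether reads were shifted for the transposase, how duplicates were treated or which mapping quality was required. The deposited peak lists have the 10 columns of the narrowPeak layout and no header. The deposited score is 10 times the −log10 q-value, shortened to a whole number, as the values show. The deposited fold is the enrichment at the summit over the caller's local background, by that layout. The deposited −log10 p-value and −log10 q-value refer to the summit, and the offset of the summit from the start was deposited in bp. The largest q-value was 0.0498 in S and 0.0499 in L, so weaker regions are absent from these lists. Peak numbers ran without a skipped number to 37414 and 24770. The number of reads per library is unknown, since peak lists hold no counts.

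The 2 QTL lists are the authors' deposited table of their own results, with TRUE, FALSE or NA in 4 unnamed columns and no header. They hold no effect size, p-value, gene or per-donor value. The initials S and L match the titles of the infected samples, while the meaning of the number 2 in their names is not given in the sources used here. Indicators 1, 2 and 4 are NA at the same positions. The meaning of NA is not given in the sources used here; a position is called tested for an indicator where that indicator is TRUE or FALSE. The L2 list ends within a line, which was left out, and was used up to that line. Sharing of positions and runs in 1 list alone were therefore compared over shared positions. All other S2 values are over all S2 positions unless stated, and L2 values are over the part held.

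Overlap was counted at 1 bp or more. Strength was ranked by −log10 q within a list. Chance overlap came from 1000 circular shifts within chromosomes. Intervals of shares are exact Clopper-Pearson intervals at 95%. For shares of QTL positions they count linked positions singly and are too narrow. Correlations across autosomes used 100000 permutations, two-sided, and protein-coding gene counts per chromosome from a gene table of assembly GRCh38, of which no coordinate was used. Gene density was divided by the last genotyped position of each chromosome in hg19.

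The planned in-peak test needed genes and weaker records, which the lists do not hold. In its place, the middle TRUE position of each 100 kb bin was compared with all tested positions of the bin, and the exact distribution of the sum over bins gave a two-sided p. The 16 tests (2 QTL lists, 2 peak lists, 4 indicators) were adjusted together by Benjamini-Hochberg at a threshold of 0.05. On simulated data without an effect, p fell under the threshold in 2.75% of 400 runs for S2 in S peaks. For L2 in L peaks it did so in 1.25% of 400 runs. With odds of 3 it did so in 100% and 85% of 40 runs. Only these 2 of the 16 tests were simulated, with the bin counts of indicator 1. Simulated stretches were short and stayed within 1 bin, while real stretches of TRUE positions can cross bins. The simulation therefore does not show whether p is too small where bins are linked.

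The pileup at each summit and its local background were recovered from the deposited fold and −log10 p-value, assuming fold = (pileup + 1) / (background + 1) and a Poisson p. On simulated peaks the pileup came out exact in 100% of 2000 for each list, and 99.997% or more of the real peaks were solved within 0.01. The shortest peak of each list was taken as the fragment length, 138 bp in S and 162 bp in L. This assumption enters the tags per kb and bears on summits over background compared between the lists.

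Before the data were examined, the groups, the tests, the alternatives and 23 gene lists with 454 genes were fixed. The rule for named genes asked for list members with a promoter peak in 1 condition, the genes nearest to the 5 strongest peaks of each list outside the other, and the genes of the smallest QTL p-values. Without an hg19 annotation and QTL p-values, it was applied only as positions of the strongest peaks. Peaks at the genes of the fixed lists and the QTL among those genes were not analysed here. The other regions named, such as dense windows and runs of TRUE positions (joined within 100 kb), were chosen after their values were seen. Alternatives covered stricter peaks, overlap rules, lists of equal length, merged or widened peaks, the histocompatibility region and other chance values.

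Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1.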

Results

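The study profiled open chromatin by ATAC-seq, in which a transposase inserts sequencing adapters where DNA is accessible, in human macrophages. The cells were grown for 7 days from blood monocytes and exposed for 2 h to Salmonella typhimurium at 10 bacteria per cell or to Listeria monocytogenes at 5 bacteria per cell. Per the labels, chromatin was profiled 12 h post infection. The labels describe 3 conditions, and the 2 infected ones were analysed here through 1 peak list each, called S and L below. The non-infected condition was not analysed here, so no value below is a change from uninfected cells. The series also holds 2 lists of genotyped positions from a quantitative trait locus (QTL) analysis, named S2 and L2, in which each position carries 4 TRUE, FALSE or NA indicators. What each indicator stands for is not given in the sources used here. The S2 list held 1030495 positions on all autosomes in the authors' deposited table. The L2 list was used only as far as position 55699868 of chromosome 2, which gave 506801 positions of the authors' deposited table. Its chromosomes are not in numeric order. The part held includes chromosomes 10, 12, 16 and 19, but no position in the largest S2 runs on chromosomes 6 and 7. Marks of L2 in those runs are therefore unknown. All coordinates are hg19, and regions are given by position because no gene annotation of that build was used.

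The first comparison asked how accessible chromatin differed in extent between the 2 infections. The S list held 37414 peaks covering 12.2 Mb, and the L list held 24770 peaks covering 8.40 Mb. The S list was thus 1.51 times as long and covered 1.46 times as much sequence. Peak widths were close, with a median of 275 bp in S and 287 bp in L. The densest 1 Mb window of S lay on chromosome 6 from 106000001 to 107000000 and held 59 S and 34 L peaks. The densest window of L lay on chromosome 11 from 65000001 to 66000000 and held 63 L and 56 S peaks. Further windows dense in S peaks lay on chromosome 20 from 48000001 to 49000000 (57 peaks, 37 in L) and on chromosome 11 from 35000001 to 36000000 (56 peaks, 30 in L). In L, the next densest were on chromosome 10 from 6000001 to 7000000 (48 peaks, 52 in S) and on chromosome 2 from 113000001 to 114000000 (47 peaks, 41 in S). With 1 list per condition these differences have no replicate check, and no p-value between the infections was computed.

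The peak sets were then compared by position. Of the S peaks, 19258 overlapped an L peak by at least 1 bp, which is 51.5% (95% exact binomial interval 51.0 to 52.0). Of the L peaks, 19208 overlapped an S peak, which is 77.5% (77.0 to 78.1). This left 18156 peaks in S alone and 5562 in L alone, a ratio of 3.26. That ratio carries the difference in list length. With the S list shortened to its 24770 strongest peaks, 58.7% of S and 58.9% of L peaks overlapped, and the counts in 1 list alone are then bound to be close (10234 and 10184). On the autosomes and the X chromosome 77.6% of L peaks overlapped an S peak, against a mean of 0.867% and a highest value of 1.08% over 1000 circular shifts of the L list. The intervals cover counting error only.

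Sharing rose with the strength of a peak, taken as its own −log10 q within its list. In S, 36.1% of the weakest decile and 85.4% of the strongest decile overlapped an L peak. In L the shares were 55.9% and 98.3%. Shared peaks were wider than the others, with medians of 347 against 217 bp in S and 313 against 226 bp in L. Their median −log10 q was 12.0 against 6.67 in S and 9.0 against 4.31 in L. Their median fold was lower in S (4.10 against 4.44) and higher in L (3.22 against 2.92).

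**Figure D1:**
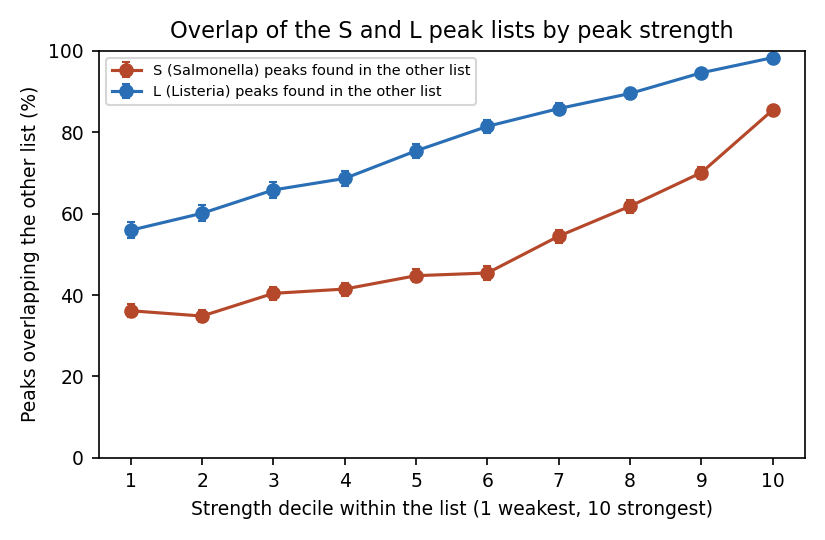
Share of peaks (%) that overlap a peak of the other list, by strength decile within each list (1 weakest, 10 strongest), with 95% exact binomial intervals as bars. The share reaches 85.4% in the strongest decile of S and 98.3% in the strongest decile of L.

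The strongest autosomal peak of S lay on chromosome 2 at 206595550 to 206596939, with a fold enrichment of 72.8 in the authors' list, and overlapped an L peak. The strongest of L lay on chromosome 12 at 24871303 to 24872894, with a fold of 34.7, and overlapped an S peak. The strongest autosomal peaks found in S alone were on chromosome 12 at 94347943 to 94348885 (fold 41.5), chromosome 2 at 201678978 to 201679541 (fold 17.8) and chromosome 11 at 82706891 to 82707650 (fold 33.6). They were followed by peaks on chromosome 7 at 148245065 to 148245537 (fold 32.5) and chromosome 3 at 115381114 to 115381784 (fold 26.4). The strongest in L alone were on chromosome 11 at 111482670 to 111483269 (fold 11.2), chromosome 3 at 119383517 to 119384177 (fold 15.0) and chromosome 4 at 173922778 to 173923074 (fold 11.7). They were followed by peaks on chromosome 3 at 149527563 to 149527826 (fold 5.89) and chromosome 2 at 204362910 to 204363169 (fold 5.36). These folds are the peak caller's own values and rank peaks only within a list.

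The balance between the lists differed by chromosome. Per 100 S peaks, chromosome 17 held 80.7 L peaks, chromosome 19 held 79.7 and chromosome 22 held 76.3, while chromosome 5 held 60.4. Across the 22 autosomes this number rose with the density of protein-coding genes (Pearson r = 0.704, permutation p = 0.00054, adjusted p = 0.00108). Spearman's rho was 0.571 (permutation p = 0.0062, adjusted p = 0.00827). Both adjustments were by Benjamini-Hochberg over 4 relations. The relation was not planned. Its p-values describe the spread over chromosomes within 1 pair of lists, not a difference between the infections. Without chromosomes 17 and 19, the farthest from the median gene density, r was 0.346 (permutation p = 0.134) and rho 0.430 (permutation p = 0.0592), so at these list lengths the relation passed the test only with those 2 chromosomes. With both lists at equal length, r without them was 0.446 (permutation p = 0.0473) and rho 0.463 (permutation p = 0.0421).

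**Figure D2:**
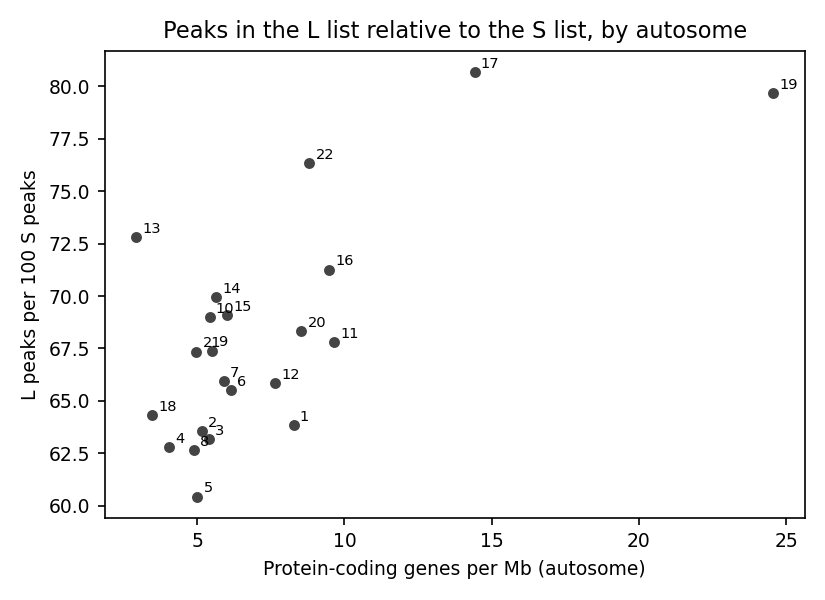
L peaks per 100 S peaks (vertical axis) against protein-coding genes per Mb (horizontal axis), 1 point per autosome, labelled by its number. Chromosomes 17 and 19 lie at 80.7 and 79.7, and chromosome 5 is lowest at 60.4.

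The QTL lists were compared next, to see how far positions marked in one were marked in the other. That S2 and L2 belong to the 2 infections is inferred from their initials only. Over the positions held of both lists, indicator 1 was TRUE at 6177 positions of S2 and 6139 of L2 in the authors' deposited table, with 3752 in common. Thus 61.1% (59.9 to 62.3) of the L2 positions of indicator 1 were also TRUE in S2 in the authors' deposited table. Indicators 2 and 4 were TRUE more often in S2, at 1743 against 863 and 3114 against 1350 positions of the authors' deposited table, which is 2.02 and 2.31 times as many. Of the L2 positions, 49.8% (46.4 to 53.2) were shared for indicator 2 and 61.3% (58.7 to 63.9) for indicator 4 in the authors' deposited table. Indicator 3 was rare, TRUE at 34 and 36 positions of the authors' deposited table, of which 19 were in common. Rotating one list against the other 1000 times left a mean of 79.9 shared positions for indicator 1, 3.15 for indicator 2 and 9.10 for indicator 4 of the authors' deposited table. Neighbouring positions are inherited together, so the intervals are too narrow, and presence in 1 list only is not a tested difference between infections. Whether both lists come from the same donors is not given in the sources used here, so the sharing cannot be taken as independent evidence.

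Over the shared positions, some runs had no TRUE position of the same indicator in the other list within 100 kb, counted from the authors' deposited table. For indicator 4 these were 184 of 302 S2 runs and 43 of 162 L2 runs. For indicator 2 they were 149 of 228 and 90 of 169, and for indicator 1 they were 143 of 490 and 167 of 513. S2 has more TRUE positions of indicators 2 and 4, which enters these counts. The run of indicator 4 with the most positions in S2 and none in L2 lay on chromosome 10 from 104581289 to 104934710, with 83 TRUE positions in the authors' deposited table. Indicator 1 was TRUE there at 62 positions of S2 and 7 of L2 in the authors' deposited table. Another on chromosome 14 from 60517037 to 60640389 held 48 such positions in the authors' deposited table. On chromosome 16 from 75386350 to 75519918, indicators 1 and 4 were TRUE at 34 and 41 positions of S2 and at 0 of L2 in the authors' deposited table. In the other direction, chromosome 12 from 112276465 to 112548563 held 52 positions of indicator 4 in L2 and 0 in S2, while indicator 1 was TRUE at 71 in both, per the authors' deposited table. Indicator 1 was TRUE in L2 alone at 56 positions on chromosome 16 from 1878493 to 2074220 and at 49 on chromosome 1 from 62901808 to 63179139 in the authors' deposited table.

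The indicators overlapped unequally within a list. Every position with indicator 2 TRUE also had indicator 1 TRUE, 3297 in S2 and 863 in L2, in the authors' deposited table. Results for indicator 2 are thus a part of those for indicator 1, not separate evidence. In S2, indicator 4 was TRUE at 52.7% of positions with indicators 1 and 2, at 11.9% of those with indicator 1 alone and at 0.363% of those without indicator 1 in the authors' deposited table. The L2 shares, over the part held, were 30.9%, 5.34% and 0.173% in the authors' deposited table. The S2 shares are over all S2 positions, so the lists are not matched here. Chromosome 6 from 25 to 34 Mb, which includes the major histocompatibility complex, held 13.4% of the S2 positions of indicator 1 in the authors' deposited table.

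The last comparison asked whether marked positions lay in accessible chromatin. Positions with an indicator TRUE in S2 lay inside peaks more often than other positions of the same 100 kb bins. For indicator 1 the share inside S peaks was 2.05% (1.80 to 2.31), against 1.11% of FALSE positions in the same bins, computed from the authors' deposited table. For indicator 2 it was 3.28% (2.69 to 3.94) against 1.14%, and for indicator 4 it was 2.88% (2.48 to 3.33) against 1.04%, computed from the authors' deposited table. The same positions were also more frequent in L peaks, at 1.73% for indicator 1, 2.79% for indicator 2 and 2.41% for indicator 4 of the authors' deposited table. The intervals count linked positions singly and are too narrow. Distance to gene start was planned as a covariate but could not be used. Closeness to genes within a bin was therefore not separated from lying in a peak, here or in the test below.

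**Figure D3:**
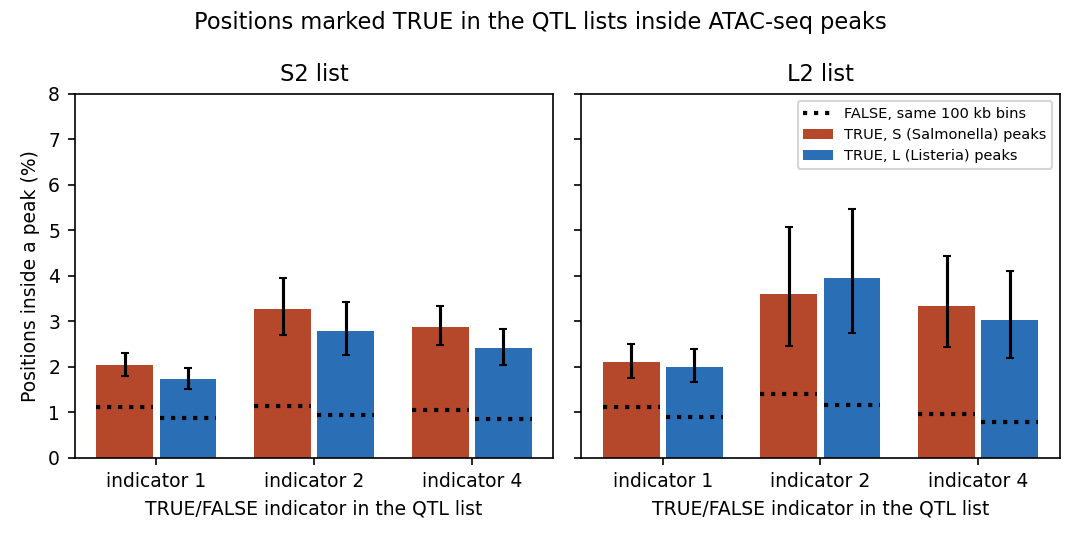
Share of TRUE positions inside S and L peaks (%, bars with 95% exact binomial intervals) for indicators 1, 2 and 4 of each QTL list, with the share of FALSE positions of the same 100 kb bins as dotted lines. S2 is shown over all its positions and L2 over the part held. The intervals count linked positions singly and are too narrow. Every bar lies above its dotted line, as for indicator 4 of S2 in S peaks at 2.88% against 1.04%.

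The test took 1 TRUE position per 100 kb bin and compared it with any tested position of that bin, two-sided, with an exact distribution. It took bins as independent, although the longest runs of TRUE positions cross bins, so p may be too small. In S peaks 47 bins were hit for indicator 1 of S2 against 17.2 by chance, a ratio of 2.73 (exact test, Benjamini-Hochberg adjusted p = 1.25e-08 over 16 tests). The ratio was 3.25 for indicator 2 (exact adjusted p = 5.18e-07) and 3.63 for indicator 4 (adjusted p = 1.28e-11). In L peaks the ratios for S2 were 2.54, 3.29 and 2.86 for indicators 1, 2 and 4 (exact adjusted p = 6.24e-06 each). For L2 in L peaks, indicator 1 had a ratio of 2.89 (exact adjusted p = 1.68e-05) and indicator 4 of 3.51 (adjusted p = 0.00371). Indicator 4 of L2 in S peaks had a ratio of 3.48 (exact adjusted p = 0.00126). S2 entered with all its positions and L2 only with the part held, so their p-values are not comparable. On the positions held of L2, indicator 1 of S2 in S peaks had a ratio of 2.41, with 22 bins hit (exact adjusted p = 0.000473 over 8 tests). Indicator 1 of L2 in S peaks (1.68, exact adjusted p = 0.0843), indicator 2 of L2 in S peaks (1.75, adjusted p = 0.421) and indicator 2 of L2 in L peaks (2.54, adjusted p = 0.089) did not pass the test. With peaks widened by 100 bp all 3 passed, at ratios of 1.88, 2.19 and 2.48. Indicator 3 hit at most 1 bin per test, or 2 with widened peaks, and is too rare to judge.

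Neither list had a peak on chromosome 6 between 28367803 and 33546494, a stretch of 5.18 Mb. At the mean autosomal density it would hold 65.7 S and 43.6 L peaks. The 5 Mb before it held 88 S and 72 L peaks, and the 5 Mb after it 101 and 88. Within it, indicator 1 of S2 was TRUE at 10.2% (9.67 to 10.7) of 14578 tested positions, against 1.16% elsewhere, in the authors' deposited table. These positions could not fall in a peak and make up 12.1% of those with indicator 1 TRUE in S2 in the authors' deposited table. The interval counts linked positions singly and is too narrow. The stretch was noticed after the values were seen.

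**Figure D4:**
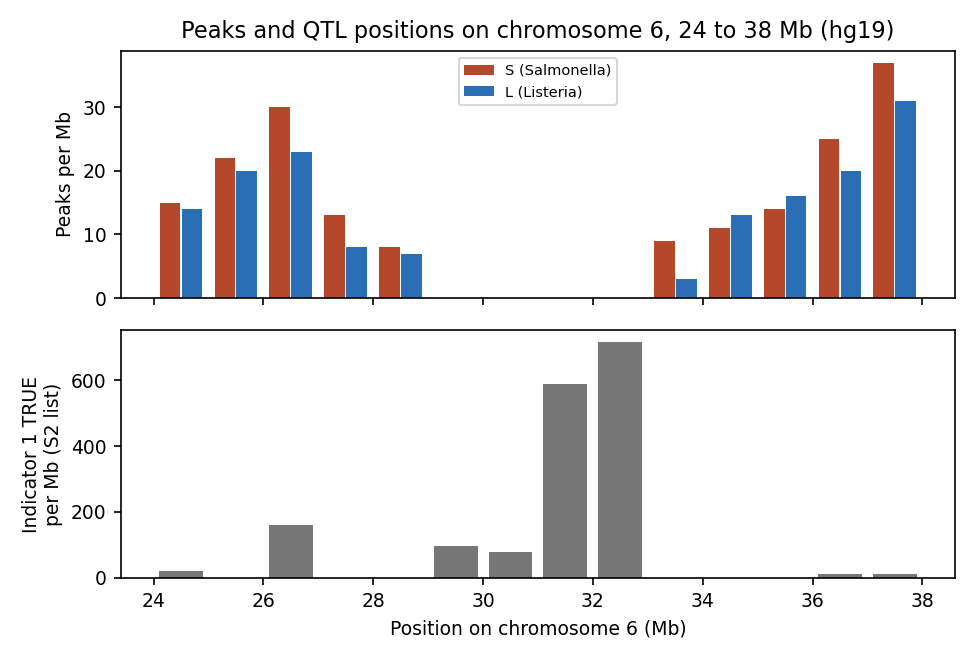
Peaks per Mb in S and L (top) and positions per Mb with indicator 1 TRUE in S2 (bottom) on chromosome 6 from 24 to 38 Mb. Both peak lists are at 0 from 29 to 33 Mb, where the S2 count reaches 715 per Mb.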

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

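The tests of tags per kb, of summit pileup, of lists per infection and of peaks on haplotype contigs were chosen only after the result was seen.

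The S list held 10 peaks on the mitochondrial genome and the L list held 0, a signal from outside nuclear chromatin that was counted within the 37414 S peaks. It is not shown to be particular to S: on chromosome 1 between 567352 and 570125, where the nuclear genome carries mitochondria-like sequence, summits stood 4497 and 3510 times above background in S and 3447 and 2686 times in L. The 4497 rests on a peak recovered within 0.0106 of its −log10 p, outside the tolerance of 0.01. At 12 positions of S2 and 6 of L2, indicator 3 was TRUE while indicators 1, 2 and 4 were NA in the authors' deposited table. The mitochondrial peaks covered 73.6% of that genome with folds of 1.11 to 1.62.

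The S list was longer than the L list. A deeper S library is argued against by the tags per kb recovered from the background, which were 0.831 times those of L, given the assumed fragment lengths. Lower signal over background in the L library could not be decided. At shared peaks the summit over its own background had medians of 26.7 in S and 21.3 in L. The median ratio of S to L was 1.17, with 71.2% of 18864 pairs above 1. The genome-wide background grows with the fragment length, assumed as 138 bp in S and 162 bp in L. The summit of a narrow peak need not grow with it, so that difference in length alone could give a ratio of this size. Over all peaks the medians ran the other way, 17.8 in S and 18.5 in L, but those are not the same peaks and the S list is longer. The infection itself stays open, because there is 1 peak list per infection.

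Neither list had a peak in 5.18 Mb of chromosome 6. Reads lost to the haplotype contigs of the build may explain it: a peak-free gap of 0.372 Mb covers chromosome 17 at 44 Mb, the site of another such contig, which is too short to decide. The window there from 43.5 to 44.5 Mb held 2 S and 2 L peaks, as few as 2.00% and 5.07% of 3353 windows. Closed chromatin over the stretch in both infections could not be excluded either. Peaks on chromosome 6 haplotype contigs numbered 2 over both lists, which cannot decide between the 2 explanations. Reads lost because they match several versions of the stretch would be missing from the contigs as well. No difference between the infections was tested here.

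The L list had relatively more peaks on gene-dense chromosomes. The weaker S peaks beyond the length of the L list are argued against, as r was 0.811 with lists of equal length (permutation p = 0.00015; 0.446 without chromosomes 17 and 19, permutation p = 0.0473). Peak strength in S is argued against too, but only through another measure, the share of S peaks found in L. With strength deciles weighted alike, its difference between the 4 chromosomes of highest gene density and the others was 6.28 points against 3.79 unweighted. Those 4 include chromosomes 17 and 19. Without these, that share had r = 0.280 with gene density (permutation p = 0.233) and rho 0.504 (permutation p = 0.0255). GC content of the reads may still contribute, since 0 genome sequences of the build were at hand. The infection stays open as untested.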

How the results depend on the processing

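The restriction of S2 to the positions held of L2, the first TRUE position of each bin and the removal of the peak-free stretch were chosen after seeing the data. No paired analysis was possible because there is 1 list per condition. Keeping only the peaks of each list above its median −log10 q left 18707 S peaks over 7.34 Mb and 12385 L peaks over 4.75 Mb. The share of S peaks overlapping L was 43.4% with a 50% reciprocal overlap, 58.7% with lists of equal length and 46.9% with the peaks above the median of each. For L peaks it was 65.5%, 58.9% and 70.8%, and 78.1% with a 200 bp gap allowed. On the positions held of L2, S2 had 6177, 1743, 34 and 3114 TRUE positions for indicators 1 to 4 in the authors' deposited table. Counting 100 kb bins, 65.2%, 45.8% and 68.9% of L2 were shared for indicators 1, 2 and 4 of the authors' deposited table. The ratio for indicator 1 of S2 in S peaks was 1.85 with every TRUE position. Of L2 in S peaks, indicator 1 passed the test with widened peaks (1.88), shifted positions (2.30) and the first position (2.38), and indicator 2 with widened peaks (2.19) and the first position (2.80). Indicator 2 of L2 in L peaks passed with widened peaks (2.48), shifted positions (4.62) and the first position (3.81). The cause was not tested. For indicators 1, 2 and 4, 60 alternative in-peak ratios lay above 1, from 1.74 to 5.11, and 51 of them kept their side of the threshold or their interval. Another 6 could not move, since equal length does not shorten the L list. Removing the peak-free stretch acts only through its edge bins and changed 1 of 6 ratios, indicator 4 of S2 in L peaks, from 2.86 to 2.96. Indicator 3 was left out as too rare, with ratios of 0 in several settings. Not run, for want of genes or p-values: promoter and distal peaks apart, promoter windows, a stricter QTL threshold, sharing by gene and all alternatives for the gene lists. Reads per library were not given and tags per kb rest on assumed fragment lengths, which limits what absence of a peak can show.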

Other observations

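The test within strength groups was planned before its result was seen, and the comparison it belongs to was noticed in the data.

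Positions with indicators 1, 2 and 4 NA lay in peaks less often than positions where these were TRUE or FALSE. The NA positions fell in S peaks at 0.167% (0.141 to 0.197) and the others at 0.815% (0.797 to 0.834), a ratio of 4.87, computed from the authors' deposited table. In L peaks the shares were 0.0849% and 0.564%, a ratio of 6.64, computed from the authors' deposited table. Bins of 100 kb with a tested position of S2 numbered 14932 for indicator 1 and 26067 for indicator 3. The NA positions thus lay partly in other regions, and these ratios were not matched by bin. Among S peaks with a tested position, taking 1 peak per 100 kb bin, 4.31% of 2553 shared peaks and 2.30% of 1738 peaks of S alone held a position with indicator 1 of S2 TRUE in the authors' deposited table. The difference was 2.01 points (permutation p = 0.00038, adjusted p = 0.00114 over 3 indicators). For indicators 2 and 4 the adjusted p was 0.0407 each.

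Peak strength in S as the whole cause of that difference is argued against for indicator 1: with classes permuted within 5 strength groups the permutation p was 0.00069 (adjusted p = 0.00207), and strength alone gave 0.155 of the 2.01 points. For indicators 2 and 4 the differences were 0.805 and 1.02 points, of which strength alone gave 0.103 and 0.228. Their adjusted p within strength groups was 0.0879 and 0.088, so the calls ended while most of each difference stayed. Shared peaks held 1.25 tested positions on average and the others 1.15, which this test did not equalise. The 2 classes also came from different bins, which were not matched. Against tested positions of the same bins, indicator 1 of S2 had an exact in-peak ratio of 2.31 in peaks of S alone (adjusted p = 0.0235 over 24 tests). In shared peaks it was 2.96. For indicators 2 and 4 the ratios were 1.99 and 2.76 in peaks of S alone, against 3.93 and 4.06 in shared peaks.

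Peaks of L alone gave mixed values beside shared peaks. Shared peaks here have the intervals of the S list, and peaks of L alone those of the L list. Of the tested positions inside peaks, indicator 1 of S2 was TRUE at 3.87% in shared peaks and 3.80% in peaks of L alone, and indicator 1 of L2 at 4.51% and 4.34%, computed from the authors' deposited table. The exact in-peak ratio for indicator 1 of S2 was 2.96 in shared peaks (adjusted p = 7.95e-07 over 24 tests) and 1.66 in peaks of L alone (adjusted p = 0.822). For indicator 1 of L2 the exact ratio was 1.90 in shared peaks (adjusted p = 0.126) and 4.93 in peaks of L alone (adjusted p = 0.00256). The 4.93 rests on 8 bins hit against 1.62 expected. For indicator 4 of L2 it was 4.15 (exact test, adjusted p = 0.0027) and 1.81, the latter from 1 bin hit. The difference between these classes was not tested. S2 entered here with all its positions and L2 with the part held.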
